A study of Homo sapiens with 12 samples.

How the data were processed

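Total RNA of 12 cultures of 2 HEK 293 Flp-In T-REx lines was labelled from 250 ng with a whole-transcript kit and hybridised to Affymetrix arrays, per the labels' protocols. The values are log2 levels deposited by the authors, 1 column per array, made with RMA per the submitters' processing notes. RMA corrects background, makes the distributions of the arrays alike by quantile normalization and summarises probes into probe sets; its software and version are not given in the sources used here. The log base is not written in the file and was read from the range, 1.06 to 14.10. Because quantile normalization equalises the arrays, a change of most genes in 1 direction would not be seen. The samples were assigned to 4 groups of 3 from their titles, which call the replicates biological; what separates one replicate from another is not described further.

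The table holds 32321 probe sets. GEO's platform annotation gives 1 gene symbol for 19158 of them, several for 1388 and none for 11775. For each of 18404 genes the probe set with the highest mean was used (637 genes have more than 1), and 18376 genes matched the GRCh38.p14 RefSeq gene table by Entrez ID. No value was missing and no 2 arrays were identical. Symbols of the lists were updated through the same table.

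Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, statmod 1.5.0) as a group-means model over all 12 arrays, following the two-way layout of cell line and induction that the design text gives. Contrasts were the induction response in each line, their difference, the line difference in each state, and the 2 averaged factors. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes at 0.05. SE is the moderated standard error and intervals are 95%. Lists were tested with camera at a preset inter-gene correlation of 0.01 over 26 of 27 lists with at least 5 measured genes; the list of genes encoded in mitochondrial DNA had 0 measured members, and ERO1A was left out of all lists. The calls were repeated with a correlation estimated per list and with fry.

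The design, the lists, the alternatives and the genes to name were fixed before the data were examined. The rule named, per comparison, ERO1A, up to 10 increases and 10 decreases of largest size among genes past the threshold with non-overlapping groups, up to 4 members per list with the largest change among those past it, and 20 ER stress and oxidant response genes whatever their values. For the mutant line, 1 result under this rule is not reported here.

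The steps were tested on simulated data made from the gene means and spreads of these arrays. Every gene and array was drawn independently, without the correlation among genes or the structure among arrays of the real data. The false calls and list calls below therefore do not show how the tests behave under such correlation. For induction in the mutant line, among 18404 genes, 56 of 100 genes changed by a log2 value of 0.4 and 94 of 100 changed by 0.8 were recovered, with 7 false calls. For the difference of the responses 36 and 77 of 100 were recovered, with 3 false calls, and for the uninduced lines 50 and 95, with 9. A shift of the chaperone list by 0.2 was called in each of these comparisons.

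Replicate letters are shared by the groups. In the WT line the deviations of same-letter uninduced and induced arrays from their group means correlated with r of 0.391, 0.139 and 0.246. The letters were taken to pair these arrays because each value was above 0.1. The main model held no replicate block, so its WT line results do not use this pairing. The correlations come from the data, since no label ties the letters to a day or batch. In the mutant line they were 0.117, -0.143 and -0.0192, and no pairing was assumed.

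Alternatives were a replicate block, arrays centred on their medians, dim genes left out (mean log2 level at or below 6.39), the mean of a gene's probe sets, a prior with trend and robust fitting, array weights, an ordinary two-way analysis of variance, all probe sets, the arrays of a comparison alone, and leaving out each array. Several alternatives were added after seeing the data. The first left out the 2 arrays at the ends of the first component of the deviations from the group means. Others left out chromosomes 5, 13 and 21, used a block in the WT line's arrays alone, or tested lists without shared members or with centred arrays. The last were adjustments over the genes called for averaged induction or over as many with its largest changes. Figures were drawn with matplotlib 3.10.9.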

Results

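RNA levels were measured on 12 arrays of human embryonic kidney cells that carried an inducible copy of Ero1α (gene ERO1A), the oxidase of the endoplasmic reticulum (ER) that reoxidises protein disulfide isomerase while proteins fold. The HEK 293 Flp-In T-REx line has a single landing site for a transgene under a doxycycline-controlled promoter, and 2 stable lines were made from it. The WT line carried wild-type Ero1α. The mutant line carried Ero1α-C104A/C131A, in which cysteines that take part in the regulatory disulfides of the enzyme were replaced by alanine, a change known to make the oxidase more active. Each line was left uninduced or was induced with doxycycline for 24 h, with 3 biological replicates, named A, B and C, in each of the 4 groups. The values were log2 RMA levels, and 18404 named genes were tested. Array medians lay between 6.36 and 6.43, and arrays of the same group correlated across probe sets with r of 0.992 to 0.996. The number of arrays limits the precision. No array of doxycycline-treated cells without a transgene was analysed here, so effects of the drug and of the transgene were not separated.

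ERO1A itself was examined first, because it checks the labels. Its probe set rose 5.38-fold on induction in the mutant line (95% interval 4.88 to 5.93, adjusted p = 3.08e-09, limma) and 4.37-fold in the WT line (log2 change 2.13 ± 0.06, SE, adjusted p = 1.42e-08). The mean log2 level went from 10.55 ± 0.11 to 12.68 ± 0.01 in the WT line and from 10.12 ± 0.06 to 12.54 ± 0.07 in the mutant line (SD, n = 3 each). All 6 induced arrays lay above all 6 uninduced arrays. Without induction the level was 0.740-fold in the mutant line relative to the WT line (adjusted p = 0.000454), and with induction it was 0.912-fold, which did not pass (adjusted p = 0.178). The probe set does not tell endogenous from transgene RNA.

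**Figure D1:**
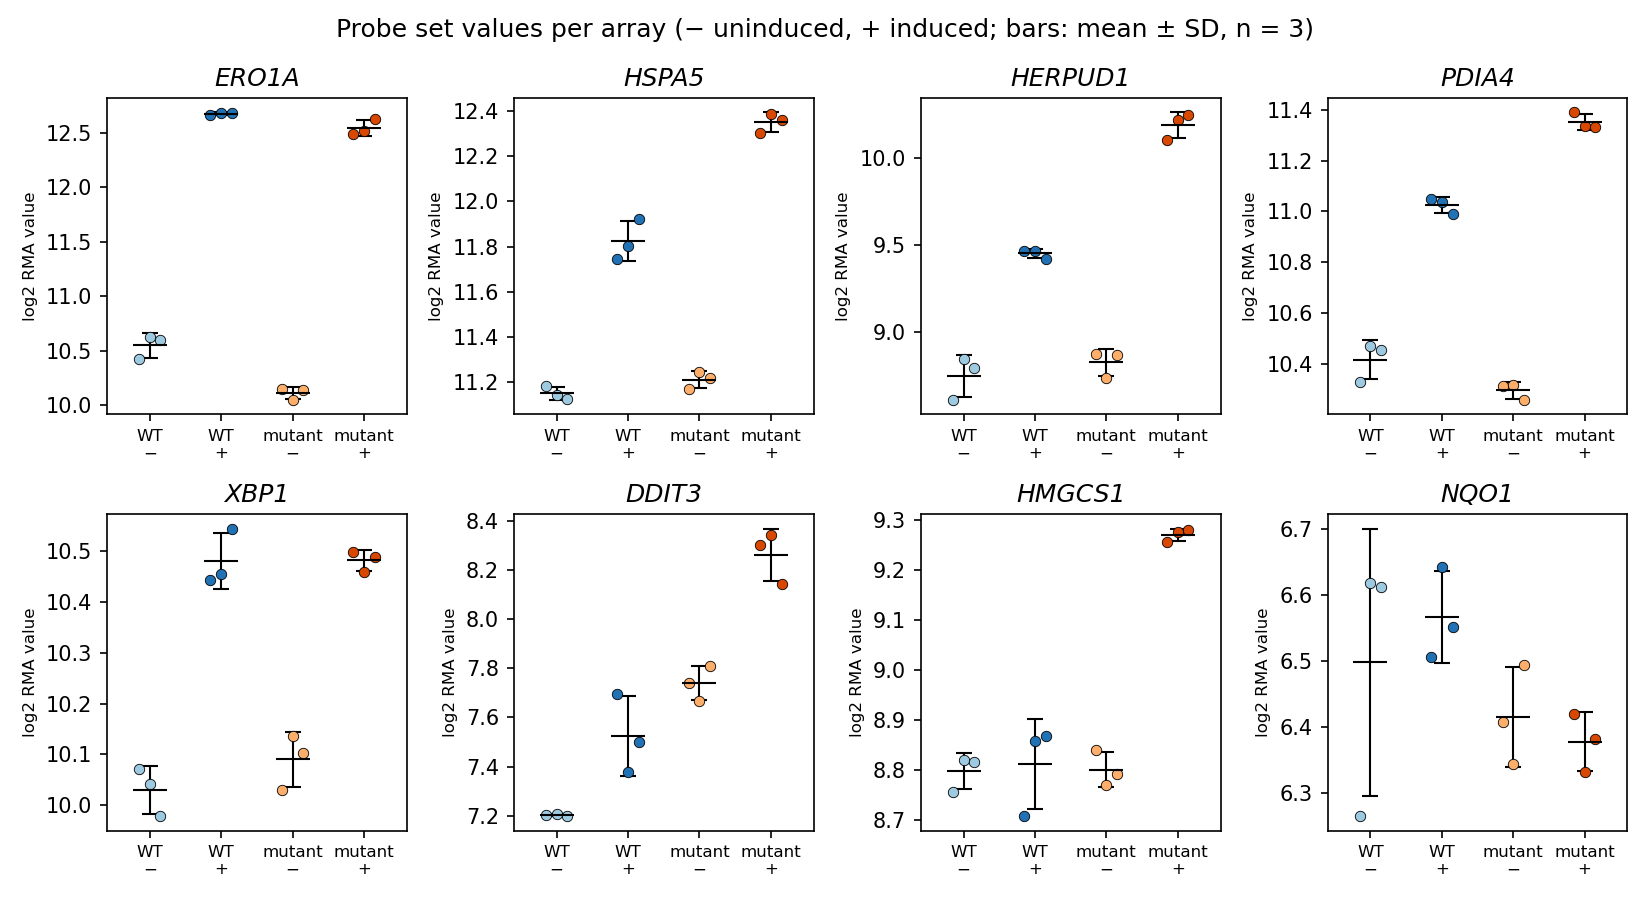
Log2 RMA values of 8 probe sets on the 12 arrays, by group (− uninduced, + induced); points are arrays, bars the mean ± SD of 3 replicates, and each panel has its own axis, which does not start at 0. ERO1A reached 12.68 in the induced WT line and 12.54 in the induced mutant line, whereas HSPA5 reached 11.82 and 12.35 in these groups.

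The first comparison asked which genes responded when the deregulated oxidase was induced. In the mutant line, ER chaperones and folding enzymes rose. After ERO1A, the largest increases were those of HERPUD1, a membrane protein of ER-associated degradation (2.57-fold, adjusted p = 1.41e-06), HSPA5, the ER Hsp70 chaperone BiP (2.20-fold, adjusted p = 1.32e-06), SDF2L1, a partner of BiP (2.16-fold), the disulfide isomerase PDIA4 (2.08-fold) and the chaperone HYOU1 (1.92-fold). They were followed by DERL3 of the degradation machinery (1.88-fold), the co-chaperone DNAJC3 (1.83-fold) and the secreted ER stress protein MANF (1.74-fold). HSP90B3P (1.64-fold) is a pseudogene of the chaperone gene HSP90B1, which itself rose 1.60-fold. The value of HSP90B3P is uncertain because its probes may also read HSP90B1 RNA, which was not tested. In all, 60 genes passed an adjusted p of 0.05, 59 higher and 1 lower, and 21 of them changed by at least 1.5-fold.

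Lists of ER stress and folding genes were then examined in the mutant line. Of 29 measured ATF6 targets and ER chaperones, 17 rose and none fell, with a median log2 change of 0.40, and 23 rose when adjusted over the list alone. CALR, the lectin chaperone calreticulin, rose 1.33-fold. Of 33 IRE1-XBP1 targets, 12 rose (28 adjusted over the list alone; median 0.26), among them SEC24D of the COPII coat (1.55-fold), DNAJB9 (1.54-fold), the translocon-associated SSR3 (1.46-fold) and XBP1 itself (1.31-fold). EDEM1, another member, was at 1.30-fold and did not pass (adjusted p = 0.335). Of 27 members of the ER-associated degradation machinery, 5 rose (9 adjusted over the list alone; median 0.12), and SEL1L rose 1.55-fold and SYVN1 1.32-fold. Of 27 ER thiol oxidoreductases, 5 rose (8 adjusted over the list alone; median 0.07), including PDIA6 (1.64-fold), DNAJC10 (1.37-fold) and ERO1B, the paralog of ERO1A (1.57-fold). These lists share members with the chaperone list. An alternative chosen after seeing the data counted the shared genes in the chaperone list alone. Camera at the preset correlation then gave an adjusted p of 3.07e-08 for the degradation list and 7.49e-05 for the oxidoreductases. This alternative was not run with an estimated correlation.

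Fewer of the PERK-ATF4-CHOP targets passed in the mutant line. Of 49 measured members, 2 rose (7 adjusted over the list alone; median 0.08): SLC7A11, the cystine transporter subunit (1.61-fold, adjusted p = 0.00524), and DDIT3, which encodes CHOP (1.44-fold, adjusted p = 0.0156). ATF4 was at 1.06-fold, ATF3 at 1.03-fold, CHAC1 at 1.11-fold, TRIB3 at 1.04-fold and the asparagine synthetase ASNS at 1.07-fold, and none of these passed. Of 20 measured cholesterol synthesis genes, 2 rose (9 adjusted over the list alone), HMGCS1 (1.38-fold) and IDI1 (1.32-fold). Of 31 NRF2 targets, SLC7A11 and UGDH (1.36-fold) rose, and the list as a whole did not shift (adjusted p = 0.435, camera). The oxidant-responsive genes HMOX1 (0.962-fold), NQO1 (0.974-fold), GCLM (1.03-fold), TXNRD1 (0.984-fold) and SRXN1 (0.911-fold) did not pass, and 0 of 31 general antioxidant genes did, by limma. The other lists held 0 genes past the threshold: cytosolic heat shock, apoptosis regulators, p53 targets, hypoxia, glycolysis, nuclear OXPHOS subunits, mitochondrial chaperones and proteases, cell cycle, immediate early genes, interferon-stimulated genes, NF-kB targets and cytokines, ribosome biogenesis, extracellular matrix, and the fibroblast, leukocyte, endothelial, epithelial and neuronal markers. Adjusted over the list alone, 1 cell cycle gene passed.

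With camera, 6 of 26 lists shifted in the mutant line, all upward: the 3 branches of the unfolded protein response, ER-associated degradation, the oxidoreductases and cholesterol synthesis. With a correlation estimated per list, 5 of these calls held, and that of the PERK-ATF4-CHOP list was lost (adjusted p = 0.0724 with an estimated correlation). The count of 60 genes fell to 38 without C104A/C131A uninduced A, 36 without C104A/C131A uninduced B and 37 without C104A/C131A induced B, and to 20 when the 6 arrays of this line were fitted alone. It rose to 91 without dim genes and to 105 with a mean-dependent, robust prior. At an unadjusted p of 0.05, 1082 genes passed, against 920 by chance, and 11.5% of genes had groups that did not overlap, against 10% by chance.

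The second comparison gave the response to wild-type Ero1α at a similar ERO1A level. Many of the genes just named rose here too, most of them by less, which choosing them for large changes in the mutant line favours. DNAJB9 (1.64-fold, adjusted p = 0.0071, limma) and XBP1 (1.37-fold) rose by slightly more than in the mutant line. HERPUD1 rose 1.63-fold (adjusted p = 0.00162), HSPA5 1.59-fold (adjusted p = 0.000597), SDF2L1 1.57-fold and PDIA4 1.52-fold. SEC24D rose 1.46-fold, CDK2AP2 1.46-fold, HYOU1 1.42-fold, PLPP5 1.41-fold and SSR1 1.27-fold. HSP90B1 rose 1.24-fold and CALR 1.21-fold, both at an adjusted p of 0.047. In all, 21 genes rose and 0 fell, 6 of them by at least 1.5-fold, and 820 genes passed an unadjusted p of 0.05, against 920 by chance. The groups did not overlap for 9.1% of genes, against 10% by chance.

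By list in the WT line, 7 of 29 ATF6 targets and ER chaperones rose (21 adjusted over the list alone; median log2 change 0.25), as did 4 of 33 IRE1-XBP1 targets (20 adjusted over the list alone; median 0.18), 2 of 27 degradation genes (HERPUD1 and DERL3; 5 adjusted over the list alone) and 1 of 27 oxidoreductases (PDIA4; 7 adjusted over the list alone). ERO1B was at 1.25-fold and did not pass (adjusted p = 0.972). No PERK-ATF4-CHOP gene passed (2 adjusted over the list alone): DDIT3 was at 1.25-fold (adjusted p = 0.567), ATF4 at 1.06-fold, TRIB3 at 1.12-fold, ASNS at 1.08-fold, CHAC1 at 1.02-fold and ATF3 at 0.981-fold. EDEM1 was at 1.03-fold. No NRF2 target passed (1 adjusted over the list alone), and HMOX1 was at 1.03-fold, NQO1 at 1.05-fold, GCLM at 0.986-fold, TXNRD1 at 0.970-fold and SRXN1 at 0.933-fold.

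Camera gave 8 shifted lists in the WT line, the 5 ER stress and folding lists upward and 3 downward. With an estimated correlation, 2 held: ATF6 targets and ER chaperones (adjusted p = 4.8e-05 with an estimated correlation) and IRE1-XBP1 targets (adjusted p = 0.024). WT uninduced A and C104A/C131A induced B lay at the ends of the first component of the deviations from the group means. Without them the IRE1-XBP1 call was lost (adjusted p = 0.181 with an estimated correlation, median 0.17). The other adjusted p values with an estimated correlation were 0.126 for both the degradation list and the oxidoreductases, 0.324 for PERK-ATF4-CHOP, 0.481 for both cell cycle and ribosome biogenesis, which had moved down, and 0.254 for cytosolic heat shock, also down. Without WT uninduced A, camera gave 13 shifted lists. The count of 21 genes fell to 9 without WT uninduced B, 12 without WT induced B and 11 without WT induced C. It fell to 13 with arrays centred on their medians and to 1 (ERO1A) when the 6 arrays of this line were fitted alone, and rose to 43 with the mean-dependent, robust prior and to 153 with array weights.

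The 2 responses were then set side by side. Leaving ERO1A out, 58 genes rose in the mutant line and 20 in the WT line, and 19 genes were in both sets, against 0.063 for independent sets. The sets are not independent, because both tests use the same estimate of each gene's spread, which can add to the overlap. With the 6 arrays of the WT line fitted alone, ERO1A was the only gene to pass there. With no other gene called, that fit cannot show how much the shared estimate added to the overlap. Of the 60 genes past the threshold in either line, 59 were higher after induction in both lines and 53 had the larger log2 change in the mutant line. As most of them were chosen by passing in the mutant line, this choice itself favours a larger change there. The single gene that passed in the WT line alone was AMIGO3 (log2 change 0.38 against 0.12 in the mutant line), named here after its values were seen. Across the genes past the threshold in either line the log2 changes correlated with r = 0.676 (Spearman 0.551), and across all 18403 genes other than ERO1A with r = 0.064. The latter was -0.0332 without C104A/C131A induced A and 0.195 without C104A/C131A induced B. Genes are not independent replicates, so no p is attached to these.

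**Figure D2:**
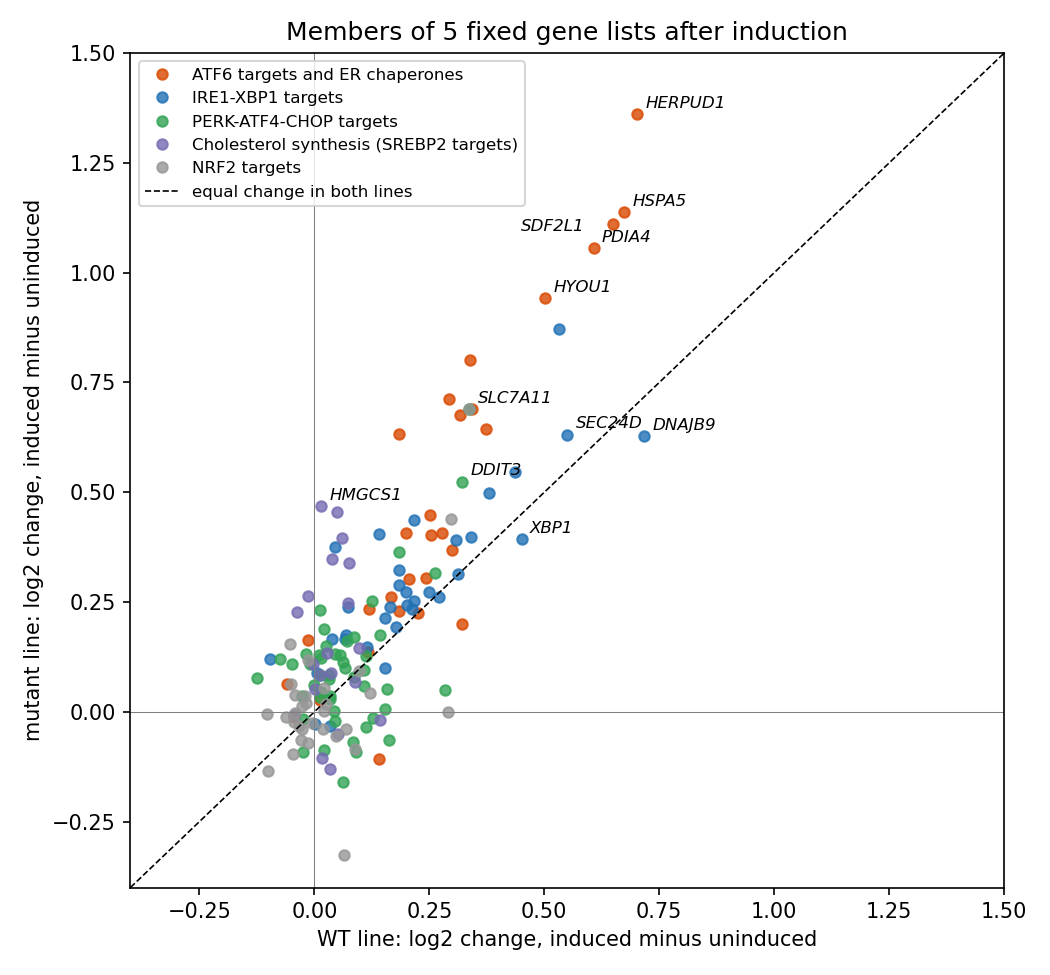
Log2 change on induction in the WT line (x axis) and the mutant line (y axis) for the measured members of 5 gene lists; each point is a gene and the dashed line marks equal change. HERPUD1 lay at 0.70 in the WT line and 1.36 in the mutant line, and XBP1 at 0.45 and 0.39.

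Whether the mutant line responded more was tested as the difference of the 2 responses, the interaction of cell line and induction. The increase was larger in the mutant line by a log2 difference of 0.66 ± 0.10 (SE) for HERPUD1, 0.46 ± 0.08 for HSPA5, 0.45 ± 0.07 for PDIA4 and 0.36 ± 0.07 for HSP90B1. It was not larger for XBP1 (-0.06, 95% interval -0.22 to 0.10) or DNAJB9 (-0.09, 95% interval -0.37 to 0.19). ERO1A itself rose more in the mutant line, by 0.30 (95% interval 0.10 to 0.50), from its lower uninduced level. CALR differed by 0.13, EDEM1 by 0.33, ERO1B by 0.33, DDIT3 by 0.20 and ATF4 by -0.01. Over all 18404 genes, 0 passed the adjusted threshold with limma, the smallest adjusted p being 0.185. An unadjusted p under 0.05 was reached by 774 genes, fewer than the 920 of chance. The ordinary two-way analysis of variance also called 0. Other settings did call some genes: 7 without dim genes, 9 with the mean-dependent, robust prior and 4 with array weights. HERPUD1, HYOU1, PDIA4 and DERL3 were among those in each of these 3 settings. HSPA5, PDIA6 and the cholesterol synthesis gene HMGCS1 were called in the first 2. The log2 change of HMGCS1 was 0.47 in the mutant line and 0.01 in the WT line.

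As a list, the ER chaperones had a larger response in the mutant line by camera. Whether chance is excluded for this list depends on the measure, as described below. The median log2 difference over 29 ATF6 targets and ER chaperones was 0.15, with an adjusted p of 2.76e-18 by camera and 0.00106 with an estimated correlation. Adjusted over the list alone, 11 members had a larger response in the mutant line and none a smaller one. Camera also called IRE1-XBP1 targets (median 0.07, 0 adjusted over the list alone), ER-associated degradation (0.07, 4 adjusted over the list alone), oxidoreductases (0.06, 2 adjusted over the list alone) and cholesterol synthesis (0.09, 5 adjusted over the list alone). These 4 calls were lost with an estimated correlation (adjusted p = 0.66, 0.203, 0.425 and 0.201 in that order). The oxidoreductase call was also lost when genes shared with the chaperone list were left out of it (adjusted p = 0.331, camera). For PERK-ATF4-CHOP targets the adjusted p was 0.052 (0 adjusted over the list alone). In a test chosen after seeing the data, the difference was adjusted over the 87 genes with the largest averaged change on induction, taken by size. Of these, 15 passed, all with the larger response in the mutant line. They included DERL3, HERPUD1, HSPA5, HYOU1, PDIA4 and PDIA6, each at an adjusted p of 0.00123 in limma, and ERO1A itself (adjusted p = 0.0378). Over the 87 genes called for averaged induction 20 passed, but that choice favours genes with a small spread, which lowers their p.

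The lines also differed without doxycycline, and by far more genes. LCP1, which encodes the actin-bundling protein L-plastin, was at 0.0173-fold in the mutant line (log2 levels 5.26 and 11.11, adjusted p = 2.41e-13). The membrane protein gene CD99 was at 0.0649-fold, PUDP at 0.125-fold, the angiomotin gene AMOT at 0.129-fold, and the zinc-finger genes ZNF730 and ZNF738 at 0.130-fold and 0.144-fold. STS, for steroid sulfatase, PXDN, for peroxidasin, MIR221 and ZNF676 were also among the 10 largest decreases. CEBPE, a transcription factor of myeloid cells, was 14.6-fold higher, LRRC7 9.77-fold, the synaptic vesicle gene SYT1 6.97-fold and the transcription factor SNAI2 6.05-fold, followed by B3GALT1, CHRM3, GALNT13, KRTAP19-5, GHR and KRTAP21-2 at 4.34 to 5.13-fold. In all, 1996 genes were higher and 1938 lower (3934 together), 637 of them by at least 1.5-fold, and 37.4% of genes had groups that did not overlap, against 10% by chance. The count was 6643 with array weights.

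ER stress genes went in both directions in this baseline comparison. Lists and named genes were not tested here with the unevenly shifted chromosomes, described below, left out. HSPA5 was at 1.04-fold, HERPUD1 at 1.05-fold, HSP90B1 at 0.971-fold, CALR at 0.988-fold, PDIA4 at 0.920-fold and XBP1 at 1.04-fold, and none of these passed. HYOU1 was 1.63-fold and SIL1 1.37-fold higher, whereas DNAJC3 was at 0.636-fold and HSPA13 at 0.417-fold. Of the 29 ATF6 targets and ER chaperones, 4 were higher and 3 lower. Of 49 PERK-ATF4-CHOP targets, 12 were higher and 6 lower, and camera did not call this list (adjusted p = 0.23). DDIT3 was 1.45-fold, ATF3 1.29-fold, TRIB3 1.27-fold and SRXN1 1.33-fold higher, and PYCR1 of proline synthesis 3.04-fold, while TXNIP was at 0.453-fold. Immediate early genes were higher as a group: 17 of 24 were higher and none lower (17 adjusted over the list alone), with DUSP1 at 2.32-fold, CCN2 at 1.82-fold, MYC at 1.75-fold and EGR1 at 1.62-fold (adjusted p = 1.06e-10 by camera, 0.0279 with an estimated correlation). Camera also called hypoxia genes, with NDRG1 at 2.23-fold and LOX at 1.96-fold (9 of 27 higher, adjusted p = 0.463 with an estimated correlation), and ribosome biogenesis (6 of 22 higher, adjusted p = 0.683 with an estimated correlation). Camera on line differences was chosen after seeing the data. The small heat shock gene HSPB1 was 3.82-fold higher.

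Of 10 measured leukocyte markers, LCP1, LYZ (0.712-fold) and CORO1A (0.749-fold) were lower, CD68 (1.69-fold) was higher, and PTPRC, which encodes the leukocyte antigen CD45, differed by a log2 value of 0.07. Among fibroblast markers, LUM was higher (3.06-fold, 1 of 10). Among epithelial markers, the keratins KRT19, KRT8 and KRT18 were higher (3 of 12). Of 17 neuronal markers 1 was higher and 4 were lower, SYP by most (0.580-fold), and 0 of 9 endothelial markers differed.

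With both transgenes induced, 1982 genes were higher and 1997 lower in the mutant line (3979 together), and 1526 higher and 1370 lower genes were shared with the uninduced comparison, against 215 and 210 for independent sets. These sets too use the same estimate of each gene's spread, which can add to the overlap. The log2 differences of the 2 states correlated across genes with r = 0.858. LCP1 was at 0.0199-fold and CEBPE 20.8-fold higher. NECTIN3 (4.53-fold) and ULK2 (0.293-fold) joined the genes with the largest differences. The ER chaperones now differed in 1 direction: 13 of 29 were higher and none lower (16 adjusted over the list alone), with HYOU1 at 2.21-fold, HERPUD1 at 1.67-fold, SDF2L1 at 1.48-fold, HSPA5 at 1.44-fold, PDIA4 at 1.25-fold and HSP90B1 at 1.25-fold. XBP1 was at 1.00-fold. DDIT3 was 1.67-fold and ERO1B 1.38-fold higher, and HMGCS1 1.37-fold. Camera called 14 lists, of which immediate early genes (adjusted p = 0.0293) and ATF6 targets and ER chaperones (adjusted p = 0.0241) held with an estimated correlation; for the other 12 that adjusted p was 0.165 or more.

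Averaged over the lines, induction raised 87 genes and lowered 0, with 1016 at an unadjusted p under 0.05 in limma. Averaged over induction, 5895 genes differed between the lines, 2817 higher and 3078 lower in the mutant line.

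The line difference was uneven along the genome, which was examined after seeing the data. Chromosomes were taken from the GRCh38.p14 gene table, and genes above the median probe set level were used. On chromosome 13 the median log2 difference was -0.59 without and -0.55 with induction, and 144 of 202 genes were lower and 8 higher in the uninduced mutant line. On chromosome 5 it was 0.35 and 0.39, with 353 of 484 genes higher and 4 lower. On chromosome 21 it was -0.21 and -0.19. The medians of the other 20 chromosomes lay between -0.09 and 0.04 without induction. With chromosomes 5, 13 and 21 left out, 3162 genes differed between the uninduced lines. LCP1 lies on chromosome 13. Named genes and gene lists were not tested again without chromosomes 5, 13 and 21. The regional pattern may therefore contribute to their line differences.

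**Figure D3:**
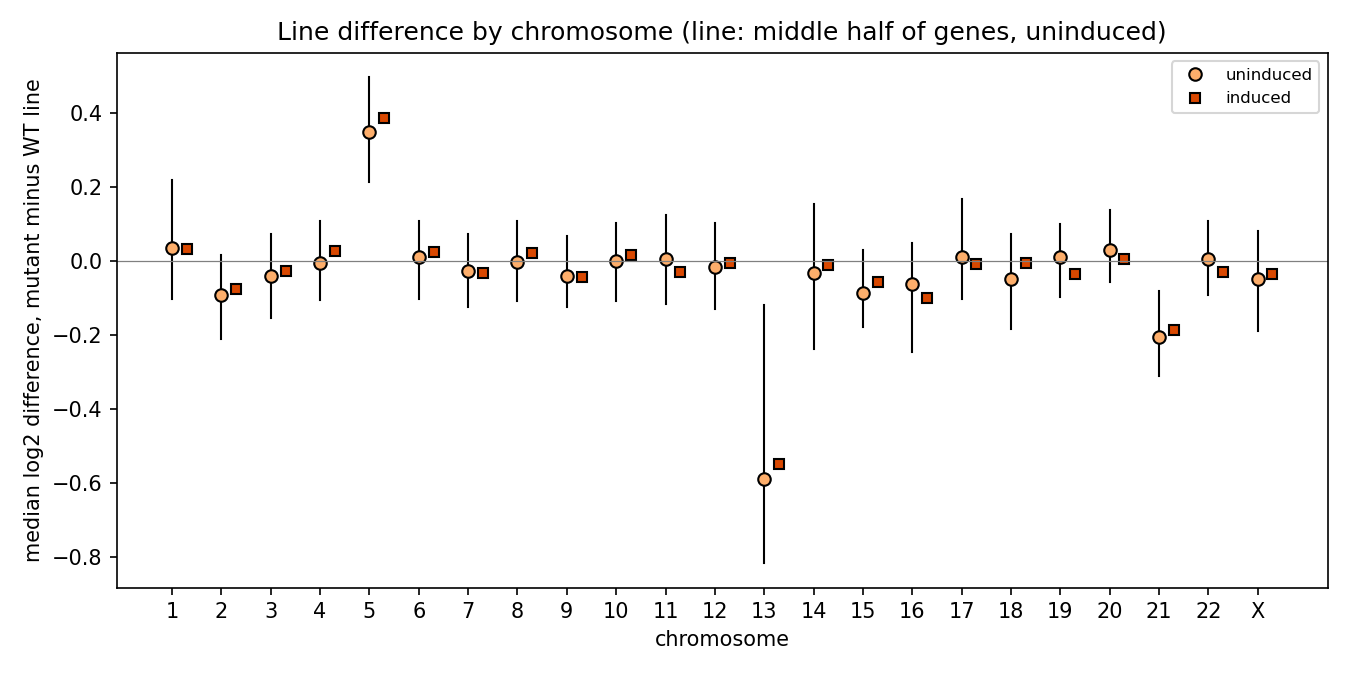
Median log2 difference between the lines (mutant minus WT) of the genes on each chromosome; circles are uninduced cells with a line over the interquartile range of the genes, and squares are induced cells. Chromosome 5 lay at 0.35, chromosome 13 at -0.59 and chromosome 21 at -0.21 in uninduced cells.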

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

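Of the tests in this part, those of transgene level, of the 2 deviating arrays, of the lines as such and of exchanges that part the WT line's same-letter arrays or cover all lists were chosen after the result was seen.

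The difference between the 2 induction responses was picked up for 5 gene lists by camera. The median log2 difference, mutant minus WT line, was 0.148 for ATF6 targets and ER chaperones, 0.089 for cholesterol synthesis, 0.074 for IRE1-XBP1 targets, 0.068 for ER-associated degradation and 0.055 for ER thiol oxidoreductases. With an estimated correlation the chaperone list alone passed (adjusted p = 0.00106). Probe sets outside the named genes also held signal: 11 of 13163 rose on induction in the mutant line, 2 with several symbols and 9 with none, by a log2 value of up to 1.18, and 1 fell in the WT line, by 0.77 on the log2 scale. Their genes were not examined.

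For the chaperone list, exchanging the induction labels within each line, after subtracting the averaged induction effect, gave an absolute median difference as large in 1 of 100 exchanges, the real one. The highest other was 0.142, so that for this list taken alone chance was excluded, by a narrow margin. The highest other was also 0.142 over the 80 exchanges that, like the real labels, part the same-letter arrays of the WT line. The list was, however, followed up as the strongest of 26. Set against the largest absolute median difference of any list, 25 of 200 exchanges, and 2 of those 80, reached 0.148, so by size chance was not excluded over every exchange. Set against the smallest camera p of any list, only the real labels among the 200 exchanges went as low, with the preset and with the estimated correlation. Whether chance is excluded over all lists therefore depends on the measure and, by size, on whether the letters do pair the arrays of the WT line. A higher ERO1A RNA level in the induced mutant line is argued against: with both transgenes induced, the upper bound of the log2 difference, mutant minus WT, was 0.008. The log2 increase of ERO1A was itself larger in the mutant line, by 0.301 (95% interval 0.102 to 0.501), from a lower uninduced level. A response that follows this increase, not the level reached, was not tested and stays open. The 2 arrays at the ends of the first component of the deviations, WT uninduced A and C104A/C131A induced B, did not make the difference. It was 0.174 without them (adjusted p = 0.00291 by camera with an estimated correlation). With 1 line per construct, a difference between the 2 lines other than the substitutions cannot be told apart from the substitutions themselves, and 3934 genes differed before induction. The larger response may therefore come from the substitutions, the explanation the design names, or from another property of the line; protein level and oxidase activity were not measured here.

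For the counts, other splits of the arrays were compared. With 10 splits of 6 arrays a share under 0.05 cannot be reached: in the mutant line the real split called 60 genes and the highest other 1, in the WT line 21 and 0, between the uninduced lines 3934 and 0, and between the induced lines 3979 and 0. For lists the real split gave 6 and the highest other 7 in the mutant line, where 3 of 10 splits gave as many, and 8 and 5 in the WT line. For the averaged factors chance was excluded: 1 of 100 exchanges, the real one, gave 87 genes for induction (highest other 13) and 5895 for the line (highest other 1). It was not excluded for the difference of the responses over all genes, where 35 of 100 exchanges gave at least the 774 genes at an unadjusted p under 0.05. The highest other was 3983, which points to a structure among the arrays; the first component held 33.7% of the variance of their deviations from the group means. Among the 80 exchanges that part the same-letter arrays of the WT line, 20 gave at least 774, up to 1516. The other exchanges mix the letters, which were taken from the data, not from a label, to pair the arrays of that line. Nor was it excluded for the number of lists in that comparison, since 10 of 100 exchanges gave 5 or more, up to 11, as did 13 of those 80.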

How the results depend on the processing

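Some settings were chosen after seeing the data. These were leaving out the 2 arrays at the ends of the first component and the block in the WT line alone. The adjustments over averaged induction genes or over genes chosen by size were also chosen then.

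ERO1A rose in both lines in the settings that tested named genes, and the log2 change stayed between 2.06 and 2.16 in the WT line and between 2.39 and 2.46 in the mutant line when single arrays were left out. Other settings gave 6923 values for 331 named genes and comparisons. Of these, 6574 kept their side of the threshold, 304 no longer passed and 44 newly passed. Among values that passed in either fit, 1 changed sign: TRAP1 between the induced lines, at -0.0197 with the mean of its probe sets. Changes of sign where neither fit passed were not counted apart from the values that kept their side. Mutant line induction, 60 genes, gave 91 without dim genes (fewer genes tested), 105 with trend and robust priors, 20 with its 6 arrays alone (fewer arrays) and 36 to 64 with single arrays left out. WT line induction, 21 genes, gave 13 with centred arrays, 43 with trend and robust priors, 153 with array weights, 1 with its 6 arrays alone and 9 to 18 with single arrays left out. The difference of the responses, 0 genes, gave 7 without dim genes, 9 with trend and robust priors, 4 with array weights and 0 whichever array was left out. The uninduced lines, 3934 genes, gave 6643 with array weights and 2988 to 4016 with single arrays left out. The induced lines, 3979 genes, gave 4510 with array weights and 3007 to 4365 with single arrays left out. With single arrays left out, the averaged factors gave 63 to 76 (induction) and 5250 to 5941 (line). Averaged induction gave 58 with centred arrays, 111 without dim genes, 120 with array weights and 126 with trend and robust priors. The averaged line gave 7252 with array weights. Shifted lists in the WT line, 8, fell to 2 with estimated correlations and 4 with fry, and were 6 to 13 with single arrays left out (13 without WT uninduced A); in the mutant line, 6, they were 6 to 9; for the difference, 5, they fell to 1 with estimated correlations and with fry and were 5 to 6. The correlation of the responses, 0.064, was 0.20 without dim genes, 0.676 over genes past the threshold in either line, and -0.0332 to 0.195 with single arrays left out, the lowest without C104A/C131A induced A. Without the 2 arrays at the ends of the first component, the mutant line gave 42 genes and the WT line 13. There were then 12 lists in the mutant line and a correlation of 0.235. For the difference with all arrays, adjustment over the averaged induction genes gave 20, a choice that favours genes with a small spread. Adjustment over as many genes chosen by size gave 15. Beyond the numbers of genes and arrays named, the cause was not tested.

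With a replicate block the counts were 54 (mutant line), 16 (WT line), 0 (difference), 3959 (uninduced lines), 4109 (induced lines), 71 (averaged induction) and 5971 (averaged line), and the list counts stayed at 6, 8 and 5. A replicate block in the 6 arrays of the WT line alone called 1 gene, as did those arrays with no block. The block changed no other count by over 1.5 times. Across all groups 9 of 18 same-letter pairs correlated above 0.1 (-0.21 to 0.391). Uninduced WT arrays correlated with induced mutant arrays at 0.311 (A), 0.246 (B) and -0.21 (C). For induced WT arrays with induced mutant arrays the values were 0.32, 0.144 and -0.126. Outside the WT line no pair of groups had every letter above 0.1, so no pairing was assumed there.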

Other observations

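The test of whole-chromosome copies and that of matched genes were chosen after the chromosome pattern was seen, but before their own results were, and the exchanges that compare 2 lists were chosen after the list medians were seen.

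Genes of chromosomes 13 and 5 differed between the uninduced lines as blocks, with medians of -0.589 and 0.348 on the log2 scale. Brightness and genomic span of the genes are argued against: genes of other chromosomes matched in both had medians of -0.032 for chromosome 13 and -0.022 for chromosome 5. A different number of copies of the whole chromosome would shift the genes before and after its middle gene alike. On chromosome 5 the genes before and after the middle gene had medians of 0.343 and 0.350. On chromosome 13 they were -0.143 and -0.705, the former between the bounds set for and against this explanation. More copies of chromosome 5 and fewer of part of chromosome 13 in the mutant than the WT line may account for the pattern. This is a hypothesis that DNA would have to test, and the differences do not tell which line changed. Probe GC content was not tested, and the labels used here give no array batch.

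Outside chromosomes 5, 13 and 21, neighbouring genes tended to differ together. Of 10347 genes, 2812 were called between the uninduced lines, and 837 neighbouring pairs were called in the same direction, against a median of 457 and a highest value of 518 in 1000 shuffles of the gene order within chromosomes (permutation p = 0.001, one-sided, the smallest these shuffles can give). Regional differences between the lines, in copy number or in chromatin, are candidate explanations that were not separated, and overlapping or related neighbours can add to the count.

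Whether the extra response of the mutant line differs between branches of the unfolded protein response stays open. The chaperone list (29 genes, median difference 0.148) and the IRE1-XBP1 list (33 genes, median difference 0.074) share no gene. As large a gap between their medians came from 22 of 200 exchanges of the induction labels within each line, and from 12 of the 80 exchanges that part the same-letter arrays of the WT line. Camera between the lists gave p = 0.0302, but it was set aside because it takes into account the correlation among the chaperone genes alone (0.0222), and that among the IRE1-XBP1 targets was 0.241. The ratio of the list medians, mutant over WT line, was 1.60 and 1.42.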
